A study of Homo sapiens with 10 samples.

How the data were processed

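RRBS libraries of MCF7 and 4 resistant derivatives (C49R, C70R, FULR and TAMR), 2 libraries per line, were analysed from the deposited files; groups and replicate numbers were taken from the sample titles. The deposited values are methylation levels as a fraction from 0 to 1, 1 per cytosine, made by the authors with BSMAP on hg19, per the submitters' processing notes; the version, filters and coverage minimum are not given in the sources used here. The files hold no read counts or coverage, so the depth is unknown, no interval from counts can be given, and the level of a cytosine may rest on few reads. The libraries list 941266 to 1789375 cytosines.

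Levels were multiplied to percent. Cytosines listed in all 10 libraries on chromosomes 1 to 22 and X were kept, the strands of a CpG were averaged, and runs of at least 5 CpGs with gaps of at most 100 bp were taken as clusters, whose level is the mean over their CpGs. Coordinates are 1-based on hg19. The design fixed before the data were examined foresaw a test on read counts, with limma on the levels as the substitute where there are none. The substitute was used: limma 3.58.1 in R 4.3.3, with 1 linear model over all 10 libraries and the line as the only term. It used empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment within each comparison. Besides the 6 main comparisons, C49R and C70R were each compared with FULR and TAMR, for the separation of the pairs and the flagged results. A call needed an adjusted p under 0.05 and a difference of at least 20 percentage points. Fitting all lines together gives 5 residual degrees of freedom; the prior added 0.743. Values are given as mean ± SD over 2 libraries, and SE is that of the moderated difference. Line levels and library distances were tested by exact permutation over the 945 ways to pair the libraries. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

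The fit was tested on simulated data: with 200 of 24222 clusters raised in FULR by 30 points it found 33.5% of them, and with a rise of 50 points 74.0%, each with 0 unchanged clusters called. For C49R it found 34.0% and 76.5%. Counts of calls therefore leave out many changes of moderate size. The raised clusters were drawn only from those with a mean level of at least 5% and room for the rise. In the data, FULR had 989 clusters higher and 98 lower at a limma adjusted p under 0.05. The adjustment is stricter where fewer clusters change, so the simulated shares need not hold for FULR.

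Named clusters are those with the 2 largest gains and the 2 largest losses per comparison with MCF7. The rule fixed before the data were examined asked for such clusters outside promoters. Without an annotation promoters could not be left out, so the named clusters may include them. The same rule was used for C49R against C70R and for FULR against TAMR after the data were seen. Enrichment by CpG density (3 classes of like size, sparse meaning at most 7.23 CpGs per 100 bp) and in 1 Mb windows with at least 5 eligible clusters, and the test of neighbours within 100 kb, were also chosen after the data were seen. Their background is the clusters that could change by 20 points, with an MCF7 level of at most 80% for gains and at least 20% for losses. CpG density counts the CpGs listed in any library, not those of the genome sequence. It therefore also depends on what the libraries covered. Unchanged lines were simulated 20 times around the MCF7 means with the residual SD of each cluster, the MCF7 libraries included. After the data were seen, differences were also taken with 1 line against one MCF7 library and another line against the other, by size only and without a test, so that they share no library. Calls were compared in the same way between the fit without one MCF7 library and the fit without the other.

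Promoters, gene lists and gene names were planned but are not analysed here, because an annotation of hg19 was not used; regions are given by position only. The alternatives tried were a difference of 10 points, logit levels (offset of 1 point), a replicate block, only the 2 lines compared, each library left out in turn, gaps of 50 bp and, for line levels, each library's own cytosines. Added after the data were seen were a variance trend, at least 3 or 10 CpGs per cluster, the median level, CpGs of the 4 libraries compared, a fit with no C70R library (these list the fewest cytosines) and line levels over clusters.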

Results

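DNA methylation was profiled by reduced representation bisulfite sequencing (RRBS), which reads CpG-rich parts of the genome after bisulfite treatment, in 5 human breast cancer cell lines with 2 libraries each. MCF7 is an established oestrogen receptor-positive line and served as the parental control. C49R and C70R are MCF7 derivatives resistant to KDM5 inhibitors known by code names. FULR is a fulvestrant-resistant derivative and TAMR a tamoxifen-resistant one; fulvestrant and tamoxifen are antioestrogens. Per the labels, MCF7, C49R and C70R were grown in DMEM with serum, and the endocrine-resistant lines in phenol red-free RPMI with charcoal-stripped serum, so that the type of resistance and the medium go together. Libraries listed between 941266 cytosines (C70R replicate 2) and 1789375 (MCF7 replicate 2). The read depth behind each level is unknown. Of 2295070 cytosines listed in any library, 459354 (20.02%) were listed in all 10, and they gave 437208 CpGs after the strands were merged. Runs of neighbouring CpGs formed 24222 clusters with a median of 7 CpGs and 109 bp. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these libraries only, which may be technical.

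The first question was whether the resistant lines differed from MCF7 in their genome-wide methylation. The mean level over the shared CpGs was 43.65% ± 0.025 (SD, n = 2) in MCF7, 43.82% ± 0.022 in C49R and 43.91% ± 0.049 in C70R. It was 46.30% ± 0.025 in FULR and 45.60% ± 0.0053 in TAMR, which was 2.65 and 1.95 percentage points above MCF7. C49R and C70R lay 0.164 and 0.259 points above MCF7, and averaged over clusters instead of CpGs they lay at -0.079 and -0.015 points, so no direction held for them. Over each library's own cytosines, a set that differs between libraries, the differences from MCF7 were larger. They were 1.048 points in C49R, 0.413 in C70R, 4.006 in FULR and 2.984 in TAMR. The SD between the 2 libraries was 0.79 points in MCF7, 0.74 in C49R, 1.00 in C70R, 0.19 in FULR and 0.59 in TAMR. The libraries of C49R and of C70R overlapped in level with those of MCF7. Over the shared CpGs the lines differed more than the replicates did (exact permutation test over 945 pairings of the libraries, p = 0.00106). That p-value is the smallest the exact permutation test can give. The same exact permutation test gave p = 0.018 over each library's own cytosines and p = 0.00423 over clusters. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333. Clusters with a level between 20 and 80% made up 12.95% ± 0.032 of all clusters in MCF7. Their share was lower in each resistant line, at 12.28% ± 0.018 in C49R, 12.36% ± 0.038 in C70R, 11.77% ± 0.050 in FULR and 12.16% ± 0.088 in TAMR (SD, n = 2). The exact permutation test (p = 0.00106) shows only that these shares differed less within lines than between them, and it does not test MCF7 against any line. The 25 mitochondrial cytosines listed in all libraries served as a check of bisulfite conversion. Their mean level was 0.286% ± 0.020 in MCF7, 0.266% ± 0.093 in FULR and 0.354% ± 0.0085 in TAMR.

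**Figure D1:**
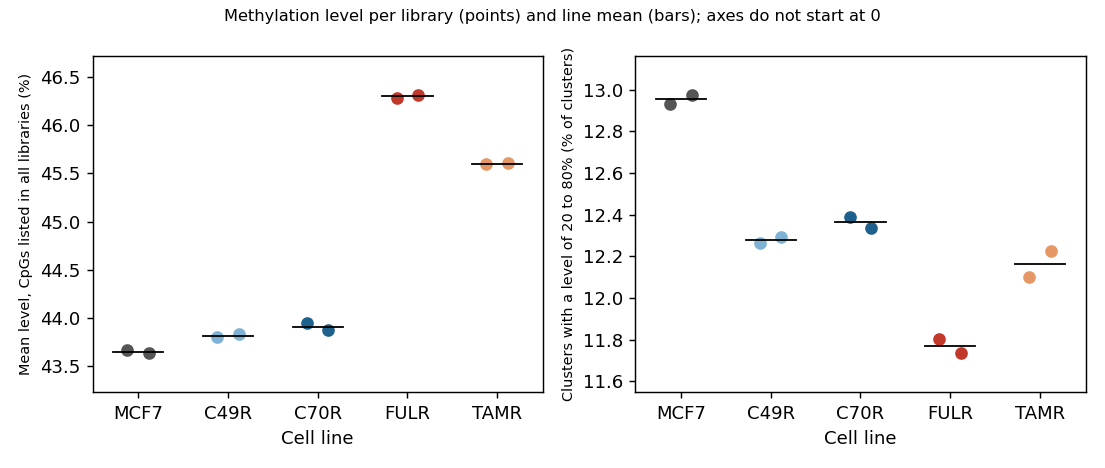
Left, mean methylation level in percent over the CpGs listed in all libraries; right, the share of clusters with a level of 20 to 80%. Points are libraries and bars line means, and the axes do not start at 0; FULR (46.30%) and TAMR (45.60%) lie above the other lines on the left, and MCF7 (12.95%) lies above the resistant lines on the right.

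On average, libraries of one line resembled each other more than libraries of other lines, but not in every pair. The mean absolute difference between same-line libraries over clusters was 2.42 percentage points (exact permutation p = 0.00106, the smallest of 945 pairings), and 9 of 10 libraries had the other library of their line as the nearest, or 8 of 10 over single CpGs. The C70R libraries differed from each other by 2.764 points, and the closest pair of a C49R and a C70R library by 2.703; over single CpGs these were 5.996 and 5.738. Between lines the mean over clusters was 2.57 points for FULR and TAMR, 2.815 for C49R and C70R, 2.82 for MCF7 and C49R, 3.30 for MCF7 and C70R, 3.598 for MCF7 and TAMR and 4.03 for MCF7 and FULR.

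C49R differed from MCF7 at 34 clusters, of which 14 were gained (higher in the resistant line) and 20 were lost. The deepest loss lay on chromosome 5 at 179106228 to 179106331 (hg19, 9 CpGs), where the level was 73.56% ± 2.22 in MCF7 and 3.90% ± 0.93 in C49R (SD, n = 2; difference -69.66 points, SE 2.01, adjusted p = 0.000831). A cluster on chromosome 8 at 144820007 to 144820157 went from 68.66% ± 5.23 to 22.84% ± 0.53 (adjusted p = 0.0295). The largest gains lay on chromosome 11 at 69515574 to 69515709, from 22.41% ± 0.68 to 67.94% ± 2.29 (adjusted p = 0.0338), and on chromosome 7 at 5597647 to 5597860, from 16.11% ± 2.02 to 57.19% ± 1.57 (adjusted p = 0.0325). Tests were made with limma over 24222 clusters, and a call needed an adjusted p under 0.05 and a difference of at least 20 points. Without C49R replicate 1 the counts were 3 gains and 11 losses, and on logit levels 6 gains and 14 losses. They were 10 and 10 on median levels, 8 and 13 with gaps of 50 bp, 13 and 24 with at least 3 CpGs per cluster, 3 and 4 with at least 10 and 0 and 0 with only these lines in the fit. A replicate block, although the replicate numbers did not pair the libraries, gave 1 gain and 13 losses. Neither named gain was called under it, while both named losses were. The chromosome 11 gain was no longer called on logit levels, with gaps of 50 bp or without any 1 of the 4 libraries, and the chromosome 7 gain with gaps of 50 bp, without either C49R library or without MCF7 replicate 1. The chromosome 8 loss was no longer called on logit levels, on median levels, without either C49R library or with no C70R library in the fit. With only the lines compared in the fit, 21 of the 22 named differences over all comparisons were no longer called, and 19 with CpGs of the 4 libraries compared.

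C70R differed from MCF7 at 148 clusters, 63 gained and 85 lost. The chromosome 5 cluster lost in C49R was also the deepest loss here, at 1.34% ± 1.90 (SD, n = 2; difference -72.21 points, SE 2.01, adjusted p = 0.000387). On chromosome 17 at 77814304 to 77814420 (7 CpGs) the level was 94.72% ± 2.64 in MCF7 and 24.29% ± 7.42 in C70R (difference -70.43 points, adjusted p = 0.011). The largest gain lay on chromosome 19 at 49118018 to 49118115, from 12.29% ± 6.53 to 75.82% ± 10.03 (difference 63.52 points, SE 6.84, adjusted p = 0.0201). The chromosome 11 cluster gained in C49R reached 80.40% ± 9.78 (difference 57.99 points, adjusted p = 0.00722). Losses gathered in the window of chromosome 17 from 77000001 to 78000000, where 7 of 49 clusters able to fall by 20 points were lost (Fisher's exact test, one-sided, adjusted p = 5.84e-05 over 484 windows). Some of these clusters lay close together and are not independent, so this p-value may be too small. Gains were most frequent in sparse clusters, those with at most 7.23 CpGs listed in any library per 100 bp. Among clusters with an MCF7 level of 5 to 80%, 44 of 60 gained clusters were sparse, against 1918 of 4169 eligible. The odds ratio was 3.28 (Fisher's exact test, adjusted p = 4.6e-05), and clusters are not independent replicates. For losses, 50 of 85 were sparse, with no difference that passed the test (adjusted p = 0.206). Without MCF7 replicate 2 the gains numbered 37. Gains and losses were 38 and 62 on logit levels, 26 and 40 on median levels, 33 and 40 with gaps of 50 bp, 136 and 147 with at least 3 CpGs per cluster, 11 and 18 with at least 10 and 0 and 0 with only C70R and MCF7 in the fit. A replicate block, although the replicate numbers did not pair the libraries, gave 42 and 65, and the chromosome 19 gain was not called under it. The chromosome 19 gain was no longer called without C70R replicate 1, without MCF7 replicate 2 or on median levels.

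FULR had the most calls, with 530 clusters gained and 10 lost against MCF7, so that 98.1% of its calls were gains. On chromosome 16 at 87890430 to 87890714 (7 CpGs) the level rose from 10.00% ± 1.37 to 95.61% ± 0.53 (SD, n = 2; difference 85.60 points, SE 3.29, adjusted p = 0.000451). On chromosome 14 at 105935411 to 105935708 (10 CpGs) it rose from 13.95% ± 4.93 to 96.47% ± 0.13 (adjusted p = 0.000697). The deepest losses were on chromosome 4 at 27086555 to 27086578, from 85.00% ± 7.07 to 40.00% ± 0.03 (adjusted p = 0.00684), and on chromosome 8 at 140630778 to 140630831, from 66.82% ± 1.58 to 32.91% ± 3.35 (adjusted p = 0.00734). Gains fell on clusters at low and middle levels in MCF7: 15.52% of the 1231 clusters at 20 to 50% were gained, 12.49% of the 1065 at 5 to 20% and 8.29% of the 1869 at 50 to 80%, against 0.4% of the 12722 below 5%. Of 479 gained clusters with an MCF7 level of at least 5%, 346 were sparse, against 1918 of 4169 eligible (odds ratio 3.5, Fisher's exact test, adjusted p = 3.04e-34). Neighbouring clusters are not independent, so the p-values of the density and window tests may be too small. The window of chromosome 16 from 88000001 to 89000000 held 13 gains among 73 eligible clusters (adjusted p = 0.000371 over 973 windows), and 11 windows passed the test. Of the gained clusters, 51.3% had another within 100 kb, against a mean of 31.9% and a highest value of 38.7% over 1000 permutations within chromosome and MCF7 level (adjusted p = 0.001, the smallest they can give). The gains numbered 349 without FULR replicate 1, 327 without FULR replicate 2 and 336 without MCF7 replicate 1; the losses numbered 4 without FULR replicate 1 and 6 without MCF7 replicate 1. On median levels there were 222 gains and 3 losses, with gaps of 50 bp 279 and 7, with at least 3 CpGs per cluster 1295 and 51, 84 and 0 with at least 10, and with only FULR and MCF7 in the fit 44 and 0. Both named losses were no longer called on median levels.

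**Figure D2:**
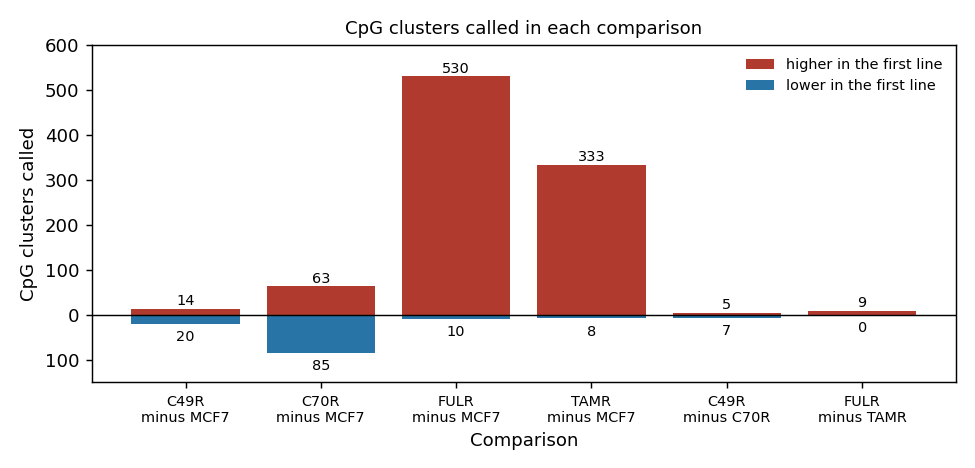
CpG clusters called in each comparison (vertical axis, number of clusters), higher in the first-named line above 0 and lower below 0. FULR and TAMR had 530 and 333 gains with 10 and 8 losses, while C70R had 63 gains and 85 losses.

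**Figure D3:**
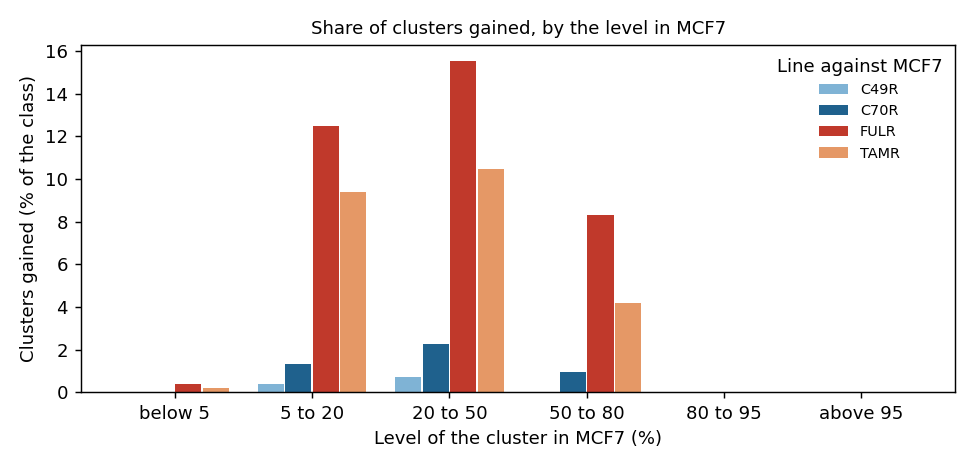
Share of clusters gained against MCF7 (vertical axis, percent of the class) by the level of the cluster in MCF7 (horizontal axis, percent), with 1 bar per resistant line. In FULR the share was highest, 15.52%, for clusters at 20 to 50% in MCF7; clusters above 80% cannot gain 20 points.

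TAMR had 333 clusters gained and 8 lost. The largest gain lay in the chromosome 19 cluster that was also gained in C70R, at 86.10% ± 7.11 against 12.29% ± 6.53 in MCF7 (SD, n = 2; difference 73.81 points, SE 6.84, adjusted p = 0.00812). On chromosome 20 at 55623077 to 55623157 the level rose from 25.22% ± 5.15 to 94.95% ± 1.15 (adjusted p = 0.000913). Losses were smaller, from 73.17% ± 1.78 to 43.03% ± 0.61 on chromosome 7 at 33731840 to 33732013 (adjusted p = 0.0237) and from 93.01% ± 0.78 to 63.48% ± 1.39 on chromosome 20 at 50078188 to 50078271 (adjusted p = 0.000913). Of 307 gained clusters with an MCF7 level of at least 5%, 230 were sparse (odds ratio 3.85, Fisher's exact test, adjusted p = 7.34e-26). The limit on p-values from neighbouring clusters holds here and for the window below. The window of chromosome 16 from 88000001 to 89000000 held 10 gains among 73 eligible clusters (adjusted p = 0.00156). The gains numbered 189 without TAMR replicate 1, 176 without TAMR replicate 2 and 210 without MCF7 replicate 1; the losses numbered 5 without either TAMR library or without MCF7 replicate 1. On median levels there were 127 gains and 4 losses, with gaps of 50 bp 165 and 6, with at least 3 CpGs per cluster 747 and 34, 60 and 1 with at least 10, and with only TAMR and MCF7 in the fit 11 and 0. The chromosome 7 loss was no longer called without any 1 of the 4 libraries or on median levels.

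The KDM5 inhibitor-resistant lines differed from each other at 12 clusters, 5 higher and 7 lower in C49R. On chromosome 17 at 77814662 to 77814890 (15 CpGs) the level was 79.41% ± 1.92 in C49R and 42.95% ± 1.13 in C70R (SD, n = 2; difference 36.46 points, SE 2.62, adjusted p = 0.027). On chromosome 11 at 65246422 to 65246553 it was 93.65% ± 1.67 and 58.23% ± 1.56 (adjusted p = 0.0252). It was lower in C49R on chromosome 16 at 2521519 to 2521672, at 23.89% ± 0.22 against 58.96% ± 4.18 (adjusted p = 0.0439), and on chromosome 4 at 3474323 to 3474499, at 11.01% ± 0.69 against 38.33% ± 0.47 (adjusted p = 0.0397). The number of calls was 6 without C49R replicate 1, 25 without C70R replicate 1 and 20 without C70R replicate 2. It was 4 on logit levels, where none of the 4 named clusters was called, and 3 on median levels, where only the chromosome 11 cluster was. It was 7 with gaps of 50 bp, 2 with at least 10 CpGs per cluster and 0 with only these lines in the fit. A replicate block also left 0 calls, although the replicate numbers did not pair the libraries. The chromosome 17 cluster was also lost as a call with gaps of 50 bp or without C49R replicate 1, and the chromosome 16 cluster without either C49R library, without C70R replicate 2 or with at least 3 CpGs per cluster. The chromosome 4 cluster was called under no alternative but the difference of 10 points.

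FULR and TAMR differed from each other at 9 clusters, all higher in FULR. On chromosome 16 at 4426242 to 4426300 the level was 75.02% ± 7.90 in FULR and 14.18% ± 0.09 in TAMR, and the cluster was listed at 0 in both MCF7 libraries (SD, n = 2; FULR minus TAMR 60.83 points, SE 3.81, adjusted p = 0.021). On chromosome 7 at 157413778 to 157414039 it was 62.71% ± 1.20 and 25.69% ± 2.43 (adjusted p = 0.021). With limma, 0 clusters were called lower in FULR. At an adjusted p under 0.05 without the limit on size, 23 clusters were higher in FULR and 5 lower. An unadjusted p under 0.05 was seen at 1798 clusters in either direction. A share of 0.05 of the 24222 clusters would reach this without any difference. The number of calls was 15 without FULR replicate 2 and 16 without TAMR replicate 1. It was 6 on logit levels, where the chromosome 16 cluster was not called, 5 on median levels, where the chromosome 7 cluster was not, and 3 with no C70R library in the fit, where neither was. With only these lines in the fit it was 0, with at least 3 CpGs per cluster 19 and with at least 10 it was 2. A replicate block, although the replicate numbers did not pair the libraries, left 1 call, and neither named cluster was called.

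The calls of the lines overlapped by direction. Of the 63 clusters gained in C70R, 62 were also gained in FULR and 56 in TAMR. Independent lists of these sizes over all 24222 clusters would share 1.378 and 0.866. Only 16887 clusters had an MCF7 level that allows a gain of 20 points. Values for independent lists of gains, here and below, are therefore too low. Of the 85 clusters lost in C70R, 0 were called lost in FULR and 2 in TAMR. Independent lists would share 0.035 and 0.028, also too low, since only 10436 clusters could lose 20 points. With only 10 and 8 clusters lost in FULR and TAMR, few losses could be shared with them. C70R lay below MCF7 at 8 of these 10 (median -11.68 points) and at 7 of these 8 (median -16.09). At the 85 clusters lost in C70R, the median FULR difference from MCF7 was 3.96 points (interquartile range -0.75 to 11.3). FULR lay above MCF7 at 60 of the 85 and was called gained at 10 of them, and TAMR lay above at 51 and was called gained at 5. Among all clusters at 20 to 50% in MCF7 replicate 1, FULR lay a mean of 10.28 points above MCF7 replicate 2. The mean was 6.93 points at 50 to 80% and 2.49 at 80 to 95%, so a rise at these 85 clusters was not particular to them. C49R shared 13 of its 14 gains and 19 of its 20 losses with C70R. It shared 14 gains and 0 losses with FULR, and also 14 and 0 with TAMR. FULR and TAMR shared 301 gains, against 7.286 for independent lists, and 4 losses. In 20 simulations of unchanged lines with one set of MCF7 libraries the overlap was 0 in each pair, but a line without changes has almost no calls to share, so this value says little about the overlap of lists with real changes. Clusters gained in all 4 resistant lines numbered 13, and 0 were lost in all 4. The differences from MCF7 had a covariance across clusters of 44.86 squared points for FULR and TAMR, 17.66 for C70R and FULR and 17.34 for C49R and C70R, where simulated unchanged lines gave means of 4.87, 4.90 and 4.89. Part of each overlap may come from the shared MCF7 libraries. In fits that keep only 1 MCF7 library, and so assume that it varies like the libraries of the other lines, lists with no MCF7 library in common still overlapped. C70R and FULR shared 32 of 37 and 336 gains or 38 of 45 and 374, depending on which line kept MCF7 replicate 1, against 0.513 and 0.695 for independent lists. FULR and TAMR shared 175 or 190 gains, against 3.243 and 3.19. They shared 0 losses either way, but these lists held only 9 and 5 or 6 and 6 losses, so this 0 says little. C49R and C70R shared 10 or 5 gains and 18 or 16 losses. In contrasts that use no MCF7 library, C49R and C70R were each lower than both FULR and TAMR at 198 clusters and higher at 1. This pairing of the lines follows the growth medium. The other ways to pair the 4 lines gave 0 such clusters, which says little. They need a call both between C49R and C70R and between FULR and TAMR, and there were only 12 and 9.

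**Figure D4:**
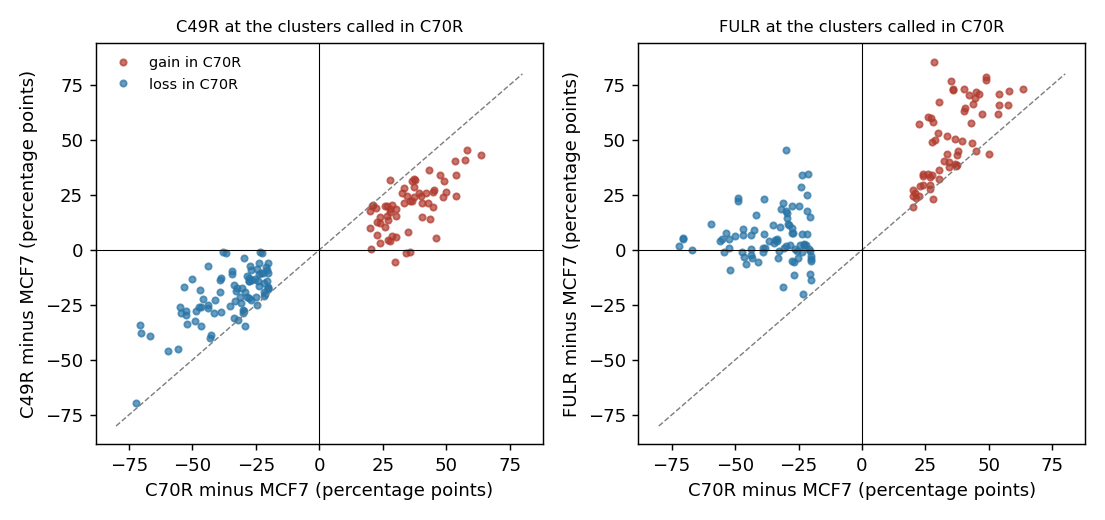
Difference from MCF7 in percentage points at the 148 clusters called in C70R, for C70R (horizontal axes) against C49R (left) and FULR (right); each point is a cluster, red for gains and blue for losses in C70R, and the dashed line marks equal differences. C49R had the sign of C70R at 145 of 148 clusters, while at the 85 clusters lost in C70R FULR had a median of 3.96 points and lay above MCF7 at 60.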

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

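Of the 13 clusters named from comparisons with MCF7, 12 also differed between resistant lines, each by a limma contrast between a pair of them (the largest called difference is given). The other 6 clusters were named because they differed between resistant lines. The tests of the patterns weighed here were chosen after the results were seen for bisulfite conversion, growth medium, the shared MCF7 libraries, the MCF7 stock and the simulated mixture; the others were set out before their values were computed.

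At clusters lost in C70R, C70R minus FULR was -74.24 points on chromosome 5 at 179106228, -71.01 on chromosome 8 at 144820007, -75.71 on chromosome 17 at 77814304, -50.64 on chromosome 17 at 77814662 and -40.88 on chromosome 11 at 65246422.

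At clusters gained in FULR, C49R minus FULR was -26.48 points on chromosome 11 at 69515574, -24.88 on chromosome 7 at 5597647, -79.3 on chromosome 16 at 87890430, -79.95 on chromosome 4 at 3474323, -73.97 on chromosome 16 at 4426242 and -38.4 on chromosome 7 at 157413778. C70R minus FULR was -67.28 points on chromosome 14 at 105935411. At clusters gained in TAMR, C49R minus TAMR was -50.27 points on chromosome 20 at 55623077 and -59.86 on chromosome 16 at 2521519. At the clusters lost in FULR, C49R minus FULR was 49.17 points on chromosome 4 at 27086555 and 32.04 on chromosome 8 at 140630778. At those lost in TAMR, C49R minus TAMR was 27.21 points on chromosome 7 at 33731840 and 29.52 on chromosome 20 at 50078188.

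Gains made up nearly all calls in FULR and TAMR. Incomplete bisulfite conversion would raise mitochondrial cytosines too. Over the 25 listed in all libraries, of unknown depth, the level differed by -0.02 points between FULR and MCF7. Between TAMR and MCF7 it differed by 0.068. Restriction to CpGs listed in all 10 libraries was not the source. With CpGs of the 4 libraries compared, FULR was at least 20 points higher at 1725 clusters and lower at 113, by size only. For TAMR these numbered 1321 and 119. Of the 152 FULR calls there, 100% were gains, but that fit held only 2 lines. On the main clusters a fit of these 2 lines also called 44 gains and 0 losses, so the share of calls says little. Growth medium and resistance cannot be told apart for the 530 FULR gains or the TAMR gains, since all libraries of these lines were grown in the other medium. C70R, grown in the medium of MCF7, was also gained at 62 of the FULR gains, which leaves open what the medium added there.

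C49R moved with C70R by a smaller amount, with a median ratio of 0.577 at the 148 clusters called in C70R. Picking clusters for a large C70R difference would lower this ratio, but at the 34 clusters called in C49R the ratio of C70R to C49R was 1.322 (interquartile range 1.124 to 1.582). The covariance of the differences was 17.34 squared points. With C49R and C70R each taken against a different MCF7 library, which leaves no library in common, it was at least 12.3. A deviation common to both MCF7 libraries would remain in both differences, so this comparison does not exclude it. A fixed mixture of MCF7 and C70R cells in the C49R cultures would put C49R at one share of the way everywhere, and 20.9% of these clusters departed from it, against at most 0.6% in simulated mixtures. A hypothesis left open is that the lines went through related changes to different extents.

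Called gains in C70R coincided with called gains in FULR, and its called losses did not. With only 10 losses called in FULR, few could coincide. C70R lay below MCF7 at 8 of these 10, by a median of -11.68 points, but both differences use the same MCF7 libraries. Error particular to one MCF7 library would not carry over to the other, while a deviation common to both libraries would. At clusters at least 20 points higher in C70R than in one MCF7 library, FULR differed from the other by a median of at least 26.7 points (lower quartile at least 8.3). Low power in FULR would leave sub-threshold losses there, but the median FULR difference at the 85 clusters lost in C70R was 3.96 points (lower quartile -0.75), and 10 of them were gained in FULR. FULR rose in general at clusters of such levels, so these values show only that it was not lower there as a set. A single loss in the MCF7 stock after all lines were derived would leave all resistant lines at one level. At the 62 common gains FULR minus C49R had a median of 25.7 points (interquartile range 14.9 to 44.7), and 32 were called. These clusters were picked for gains in FULR, which favours a higher FULR level. Lines derived at different stages of a gradual loss could also differ, so the values do not exclude a loss in the stock. A gain of methylation common to resistance may be one explanation; descent from a related part of the MCF7 population is another, and neither was tested.

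The separation of C49R and C70R from FULR and TAMR, at 199 clusters, was the highest of the 3 ways to pair the lines, 1 of which reached it, and the highest other count was 0. With 3 splits no share under 0.05 is possible. Both other splits need a call between C49R and C70R, made at 12 clusters, and one between FULR and TAMR, made at 9. Their low counts were therefore set beforehand and add no support. The split that was highest also follows the growth medium.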

How the results depend on the processing

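Counts are given as gains and losses for C49R, C70R, FULR and TAMR against MCF7, then as all calls for C49R against C70R and for FULR against TAMR. The 22 named differences gave 294 values under the alternatives. Of these, 197 stayed called, 97 kept their sign but were no longer called, and 0 changed sign. At a difference of 10 points, which can only add calls, all 22 had to stay called. There, on logit levels, with the replicate block, with a variance trend and with only the lines compared, the difference itself was unchanged. Its sign therefore could not change. Named clusters with no counterpart under a setting gave no value. With gaps of 50 bp, 10 stayed called and 3 did not, and with at least 10 CpGs, 3 stayed called and 0 did not. Gains stayed at 94.9% or more of the calls in FULR and in TAMR under each setting run. Depth is unknown, so the coverage minimums, equal-depth thinning, exclusion of the most covered CpGs and pooling of reads were not run, and neither were the promoter windows, the promoter CpG minimum or the gene list tests. Where no cause is named below, the cause was not tested.

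A difference of 10 points, which can only add calls, gave 21 and 35, 107 and 121, 770 and 41, 470 and 25, 19 and 11 clusters, and 283 for the separation of the pairs. Logit levels gave 6 gains in C49R, 38 in C70R, 4 for all calls of C49R against C70R and 6 for FULR against TAMR, and 14 losses in C49R. With only the 2 lines compared, which leaves 2 libraries per line to estimate the spread, calls numbered 44 gains in FULR and 11 in TAMR and 0 elsewhere. A gap of 50 bp gave 8 and 13, 33 and 40, 279 and 7, 165 and 6, 7 and 8.

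The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated between lines at -0.026 to 0.03. With the replicate block the counts were 1 and 13, 42 and 65, 434 and 7, 266 and 4, 0 and 1, and 160 for the separation. The calls in common with the fit without the block were 13 in C49R, 100 in C70R, 432 in FULR and 260 in TAMR.

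Leaving out 1 library assumes that the lone library of its line varies like the others. The counts ranged over 3 to 14 and 11 to 25 in C49R, 37 to 48 and 59 to 73 in C70R, 327 to 374 and 4 to 9 in FULR, 176 to 230 and 5 to 6 in TAMR, 6 to 25 for C49R against C70R and 12 to 16 for FULR against TAMR.

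The following were chosen after the data were seen. At least 3 CpGs per cluster, with 51635 clusters, gave 13 and 24, 136 and 147, 1295 and 51, 747 and 34, 9 and 19. At least 10 CpGs, with 8007 clusters, gave 3 and 4, 11 and 18, 84 and 0, 60 and 1, 2 and 2. The median level gave 10 and 10, 26 and 40, 222 and 3, 127 and 4, 3 and 5. CpGs of the 4 libraries compared, fitted alone, gave 152 gains in FULR, 34 gains and 1 loss in TAMR, and 0 calls in the other comparisons. With no C70R library, which left 35827 clusters, there were 18 and 22 in C49R, 769 and 17 in FULR, 457 and 14 in TAMR and 3 for FULR against TAMR. A variance trend moved no count by over 1.5 times.

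The level differences from MCF7 over each library's own cytosines were 1.048 points in C49R, 0.413 in C70R, 4.006 in FULR and 2.984 in TAMR. Over clusters they were -0.079, -0.015, 2.205 and 1.621, so that C49R and C70R changed sign. Leaving out 1 library gave 0.148 to 0.181, 0.224 to 0.294, 2.629 to 2.664 and 1.931 to 1.966. The same-line distance was 5.289 points over single CpGs.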

Other observations

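Of the 13 clusters gained in all 4 resistant lines, 3 each lay on chromosomes 7, 17 and 20. On chromosome 20 at 55970739 to 55970889 the mean level was 44.1% in MCF7, 75.5% in C49R, 80.8% in C70R, 94.6% in FULR and 90.5% in TAMR. On chromosome 8 at 128923680 to 128923775 the levels were 3.8%, 24.9%, 44.3%, 68.2% and 40.1% in the same order. On chromosome 7 at 476419 to 476545 they were 16.7%, 47.9%, 65.7%, 95.2% and 78.9%. These clusters were chosen after their values were seen. At the 62 clusters gained in both C70R and FULR, the median levels were 32.8% in MCF7, 55.1% in C49R, 68.6% in C70R, 83.5% in TAMR and 90.1% in FULR.

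At the 530 clusters gained in FULR, TAMR had the same sign at 528, with a median ratio of 0.787 to the FULR difference. At the 333 clusters gained in TAMR, FULR had the same sign at 333, with a median ratio of 1.137. Both comparisons use the same MCF7 libraries. In a comparison with no library in common, chosen after the data were seen, at the 881 clusters at least 20 points higher in FULR than in MCF7 replicate 1, TAMR lay above MCF7 replicate 2 at 94.2%, by a median of 20.4 points; with the MCF7 libraries exchanged it was 95.3% of 830 clusters and 22.5 points.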
